A study of Caenorhabditis elegans with 14 samples.

How the data were processed

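The series compared total and polysomal RNA of wild-type worms and of worms labelled pycr-1(wrm22), in 14 libraries sorted by their sample titles into 4 groups of 3, 3, 4 and 4. Per the labels' protocols, worms were washed and lysed with cycloheximide, which holds ribosomes on mRNA, and fractions with 3 or more ribosomes per mRNA were collected from sucrose gradients. Per the submitters' processing notes, FastQC 0.11.7, HISAT2 2.1.0, StringTie 1.3.4d and Cuffdiff 2.2.1 were used with genome build WBcel235. Settings, strandedness and the treatment of reads that map to several places were not given in the sources used here, so near-identical genes, overlapping genes and antisense pairs are uncertain.

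The deposited table gave 1 pooled FPKM per gene and group (fragments scaled by transcript length and by the fragments mapped, made by the authors before deposit), with no value per library. For each of 6 pairs of groups the authors' deposited table also gave the log2 fold change, the Cuffdiff test statistic (a score with no fixed range), the p-value and the q-value. The 2 pairs that cross strain and fraction were not used. The depth of the libraries was unknown, so no interval that needs it was computed. The median spread of a group implied by the test statistics was 0.26 for wild-type total, 0.30 for wild-type polysomal, 0.29 for mutant-labelled total and 0.27 for mutant-labelled polysomal RNA on the log2 scale. The deposited q-values equalled Benjamini-Hochberg values over 91924 tests of all 6 comparisons to within 5.24e-07. The smallest deposited p-value was 5e-05, held by 24.1% of tests, which gives the smallest q-value of 0.000207. A fold change from a group at 0 FPKM is infinite and was left out of medians.

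The 46218 gene IDs of the table fell into 41875 entries of a gene name and locus, which are called genes. Of these, 3085 carried several gene names, and 267 of those were tested in total RNA. A symbol was found for 43260 IDs. Start positions were counted from 0, and 1 was added. Then 41.3% of 14861 tested single-name entries began at the start of their gene in the Ensembl release 115 annotation of WBcel235, against 1.63% without the change, and 100% overlapped it.

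A gene passed the threshold where the authors' q-value was under 0.05, as planned for tables without values per library. The planned model per library could not be used. The standard error of a log2 fold change was taken from the ratio of the natural log of the fold to the test statistic. The variances implied this way added up across comparisons (ratio from 0.999991 to 1.00001 between the 1st and 99th percentile over 13979 entries). Normal p-values from the statistics were far larger than the deposited p-values. In total RNA, for deposited p-values from 0.001 to 0.01, the median was 0.0032 as deposited, 0.100 from the statistics and 0.00208 with each group's variance divided by its number of libraries. The errors printed after ± use the divided variance, a choice made after the values were seen.

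The difference between fractions was tested with a Wald test on the statistics as they stand, adjusted by Benjamini-Hochberg over 14302 genes, and again with divided variances. The variances of the 4 groups were added as if all libraries were independent, in the tests and in the simulated data. The labels give the total and polysomal libraries of a strain the same replicate numbers and 1 harvest per genotype and replicate, and this pairing was ignored because the table holds no values per library. On simulated data for that difference over 14302 genes, the test as planned recovered 3% of changes of 1 and 48% of changes of 2 on the log2 scale and called 0 unchanged genes. With divided variances it recovered 51% and 79% and called 9 unchanged genes. The simulated noise was itself drawn with the divided variance. The planned test was therefore bound to look conservative, and the simulated data cannot show which variance is right. The list test placed 6 of 100 unshifted lists outside the central 95%, over 14302 genes. Its noise was independent between genes and its lists were drawn at random. It therefore cannot show how often lists of genes that vary together fall outside.

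Before the data were examined, 33 gene lists, the tests, the rule for naming genes and most alternatives were fixed. The lists held proline metabolism, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, rRNA methylation, the methionine cycle, translation factors, tRNA synthetases, stress and immune responses, tissue and germline markers, collagens, lipid metabolism, oxidative phosphorylation, detoxification, autophagy, histones, ribosomal RNA, lysosome and proteasome. For each list, members that passed the threshold were counted over all genes and adjusted over the list alone. The percentile of the list median was taken among 10000 random lists of the same size matched on mean expression in 20 bins. A two-sided Fisher's exact test asked whether rises or falls were over- or under-represented, adjusted over lists, directions and 4 comparisons. Named were the proline genes, the 10 largest rises and falls among single-name genes past the threshold with at least 1 FPKM in both groups and 5 in at least 1, up to 4 members per list by absolute change (or the member with the smallest p), and up to 5 genes of opposite direction between fractions. Functional terms paired with genes in the authors' deposited table were tested for enrichment after the lists. Alternatives changed the threshold, the fold minimum, the FPKM minimum, the adjustment, the p-values, the counting unit and the centring of fold changes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Some single-gene results of the gene lists are not reported here.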

Results

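RNA was sequenced from synchronized gravid Caenorhabditis elegans on day 1 of adulthood, grown at 20 °C. Worms of the wild-type strain Bristol N2 were set beside a strain labelled pycr-1(wrm22). The gene pycr-1 encodes a pyrroline-5-carboxylate reductase, an enzyme of the last step of proline synthesis. The title of the series asks how a mutant defective in making proline responds at the level of ribosome assembly and the methionine cycle. From each strain, total RNA of the lysate and polysomal RNA were taken, the latter pooled from sucrose gradient fractions with 3 or more ribosomes per mRNA. The 14 libraries comprised 3 of wild-type total RNA, 3 of wild-type polysomal RNA, 4 of mutant-labelled total RNA and 4 of mutant-labelled polysomal RNA. The files held 1 pooled FPKM per gene and group, with no value per library, so the depth of each library was unknown and no spread between replicates could be computed from them. Every FPKM, log2 fold change and adjusted p given for a gene was taken from the authors' deposited table. The sign ± marks the SE of a log2 fold change implied by the authors' test statistics, with each group's variance divided by its 3 or 4 libraries. The labels give a harvest of about 12000 worms per genotype and replicate but do not say whether these were separate cultures, so p-values measured only the spread between these libraries. The median log2 fold change between the strains over genes at 5 FPKM or more in both groups was -0.35 in total and -0.26 in polysomal RNA. Where centring fold changes on these medians, a choice made after seeing the data, turned the sign of a list median, and for lists in which falls outnumbered rises, the centred median is given beside the median.

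The gene that the strain name marks was examined first. In the authors' deposited table, pycr-1 (listed there as M153.1, build WBcel235, chromosome X, 12146832 to 12148529, plus strand) was higher, not lower, in the groups labelled pycr-1(wrm22). Its FPKM was 4.91 in wild-type and 20.3 in mutant-labelled total RNA. The log2 fold change was 2.05 ± 0.20 in the authors' deposited table (adjusted p = 0.000207). In polysomal RNA its FPKM was 12.59 and 40.8, a log2 fold change of 1.70 ± 0.18 in the authors' deposited table (adjusted p = 0.000207). The labels do not say what the wrm22 allele changes, and a gene-level FPKM does not show which part of the transcript was present, so this value could not check the labels. All directions between the strains below therefore rest on the labels, and the groups are called mutant-labelled.

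Among the other proline genes, alh-13, which encodes the enzyme of the first steps of proline synthesis from glutamate, rose with pycr-1. Its log2 fold change in the authors' deposited table was 2.12 ± 0.41 in total RNA (9.13 to 39.7 FPKM) and 1.83 ± 0.34 in polysomal RNA (17.1 to 60.8 FPKM), over a deposited interval from 12705624 to 12813947 on chromosome X. That interval is far longer than the interval of pycr-1, so it is uncertain whether the whole value belongs to alh-13. pycr-4 fell in total RNA, by the authors' deposited table, with a log2 fold change of -0.62 ± 0.21 (adjusted p = 0.0112), and stood at -0.40 ± 0.20 in polysomal RNA (adjusted p = 0.0854). The genes for proline breakdown and ornithine aminotransferase did not pass the threshold in either fraction. Their log2 fold changes in the authors' deposited table were -0.20 ± 0.15 and -0.27 ± 0.15 for alh-6, 0.11 ± 0.21 and -0.12 ± 0.17 for prdh-1 and -0.13 ± 0.15 and -0.21 ± 0.15 for oatr-1, in total and polysomal RNA. In all, 2 rose and 1 fell of 6 tested (2 and 1 adjusted over the list alone) in total RNA and 2 rose and 0 fell of 6 tested (2 and 0 adjusted over the list alone) in polysomal RNA. The list medians were -0.0069 (0.34 when centred and 0.032 when centred on all tested genes) and -0.16 (0.093 when centred).

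**Figure D1:**
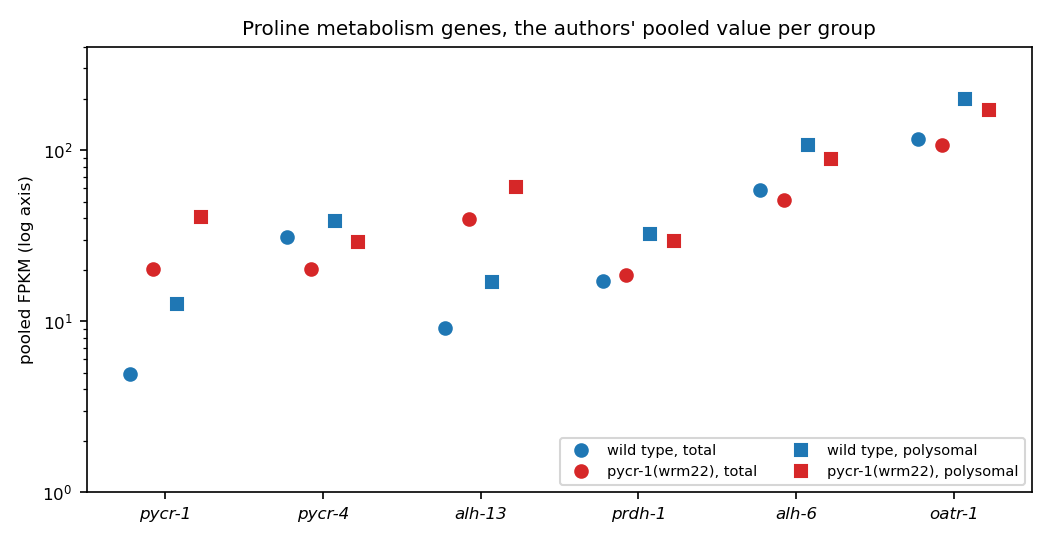
Pooled FPKM of the 6 tested proline metabolism genes on a log axis, from the authors' table, with circles for total and squares for polysomal RNA, blue for wild type and red for pycr-1(wrm22), without error bars because each group has 1 pooled value. pycr-1 went from 4.91 to 20.3 FPKM in total RNA and from 12.59 to 40.8 FPKM in polysomal RNA.

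The total RNA of the mutant-labelled worms held less oocyte, germline and embryo RNA and more RNA of most collagens than that of wild type. Weakly expressed epidermal markers were higher as well. Of the oocyte and germline genes, 0 rose and 37 fell of 40 tested (0 and 38 adjusted over the list alone), with a median log2 fold change of -0.85 (-0.50 when centred). The RNA-binding protein genes oma-2, puf-5 and mex-1, which act in the oocyte and early embryo, had log2 fold changes of -1.20 ± 0.15, -1.16 ± 0.15 and -1.22 ± 0.16 in the authors' deposited table, and meg-2 -1.31 ± 0.18. Of the collagens, the structural proteins of the cuticle, 79 rose and 19 fell of 137 tested (80 and 19 adjusted over the list alone), with a median of 1.14. Examples in the authors' deposited table were col-152 (0.885 to 5.46 FPKM, log2 fold change 2.62 ± 0.32), col-54 (0.197 to 1.20 FPKM, 2.61 ± 0.48), col-69 (0.239 to 1.21 FPKM, 2.34 ± 0.43) and col-128 (0.0951 to 0.726 FPKM, 2.93 ± 0.55), while col-135 fell by 1.99 on the log2 scale. The examples that rose were thus below 1 FPKM in wild type. Of the hypodermis and seam markers, 10 rose and 2 fell of 16 tested (10 and 2 adjusted over the list alone), with a median of 1.05, which was -0.0097 over the members at 5 FPKM or more in both groups. Members were ptr-4 (1.92 ± 0.22), mlt-11 (1.80 ± 0.35), dpy-7 (1.51 ± 0.25) and mlt-10 (1.49 ± 0.21), which act in the epidermis and the molt.

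Embryo genes were lower as well, with 2 rises and 25 falls among 43 tested (3 and 26 adjusted over the list alone) and a median of -1.23 (-0.88 when centred). The named members were below 1 FPKM in both groups, sdz-16 with 0.760 to 0.0895 FPKM, sdz-10 with 0.419 to 0.0848 FPKM, sdz-38 with 0.601 to 0.124 FPKM and lido-2, which entered the list through an older symbol, with 0.767 to 0.182 FPKM. Histone genes followed the same direction, with 2 rises and 41 falls among 67 tested (2 and 42 adjusted over the list alone) and a median of -0.71 (-0.36 when centred). Log2 fold changes in the authors' deposited table were -1.55 ± 0.17 for his-38, -1.53 ± 0.17 for his-40, -1.46 ± 0.20 for his-31 and -1.90 ± 0.49 for his-51. Histone genes are near-identical copies between which reads cannot be assigned with certainty. Sperm genes went the other way, with 43 rises and 2 falls among 92 tested (43 and 2 adjusted over the list alone) and a median of 0.40. Among them were msp-71 (11.5 to 36.01 FPKM), msp-74 (3.24 to 13.96 FPKM) and spe-29 (0.562 to 2.103 FPKM). The msp genes are also a family of near-identical copies.

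Medians of other tissue markers lay closer to 0, but high among expression-matched random lists. Of the muscle markers, 3 rose and 1 fell of 30 tested (2 and 0 adjusted over the list alone). Of the intestine markers, 5 rose and 0 fell of 19 tested (4 and 0 adjusted over the list alone). Of the neuron markers, 3 rose and 1 fell of 29 tested (1 and 0 adjusted over the list alone). Their medians were 0.15, 0.08 and 0.34, at the 100th, 99.2nd and 98.1st percentile of such lists. By the authors' deposited table, the myosin gene myo-3 had a log2 fold change of 0.57 ± 0.15, the intestinal protease gene cpr-1 0.55 ± 0.15 and the neuropeptide gene flp-9 0.69 ± 0.19. Yolk protein genes, made in the adult intestine, counted 0 rises and 3 falls among 6 tested (0 and 3 adjusted over the list alone) and had a median of -0.31 (0.037 when centred), with vit-3 at -0.43 ± 0.17.

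Among the lists of defence, rises were over-represented in innate immunity genes, 38.6% against 18.5% of other genes. They were not in DAF-16 targets, detoxification families or the intracellular pathogen response (Fisher's exact test, adjusted p = 0.250, 0.226 and 0.334). Of the innate immunity genes, 17 rose and 1 fell of 44 tested (17 and 1 adjusted over the list alone). Values in the authors' deposited table went for irg-2 from 1.61 to 12.99 FPKM, for cnc-4 from 2.102 to 16.40 FPKM, for irg-1 from 3.86 to 24.9 FPKM and for ilys-2 from 0.422 to 1.66 FPKM. Of the targets of the longevity transcription factor DAF-16, 7 rose and 0 fell of 23 tested (7 and 0 adjusted over the list alone). They included dod-3 (2.02 ± 0.33), the lysozyme gene lys-7 (71.7 to 252 FPKM, 1.81 ± 0.16), gpdh-1 (1.42 ± 0.28) and thn-1 (1.26 ± 0.31). Of the detoxification families, 42 rose and 19 fell of 186 tested (40 and 17 adjusted over the list alone), with a median of 0.18 that was -0.0051 over members at 5 FPKM or more. Those with the largest change were pgp-7 (0.0672 to 3.46 FPKM), the glucuronosyltransferase gene ugt-24 (1.28 to 23.7 FPKM), cyp-37B1 (0.101 to 1.502 FPKM) and the cytochrome P450 gene cyp-14A5 (6.89 to 101 FPKM). Of the intracellular pathogen response genes, 4 rose and 0 fell of 12 tested (3 and 0 adjusted over the list alone). Among them cul-6 stood at 1.24 ± 0.21, skr-3 at 0.71 ± 0.17 and eol-1 at 1.95 ± 0.71 in the authors' deposited table. Lipid metabolism genes went both ways, with 7 rises and 9 falls among 46 tested (6 and 9 adjusted over the list alone) and a median of -0.12 (0.23 when centred). The lipase genes lipl-1, lipl-2, lipl-3 and lipl-4 rose, with log2 fold changes of 1.03 ± 0.29, 2.24 ± 0.33, 1.46 ± 0.30 and 1.11 ± 0.40 in the authors' deposited table.

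The largest rises in the authors' deposited table were F54B8.4 (chromosome V, 15816464 to 15817143, 4.16 to 77.8 FPKM), ugt-24, parg-2, a poly(ADP-ribose) glycohydrolase gene (1.79 to 29.6 FPKM), Y58A7A.5 (3.26 to 49.4 FPKM), cyp-14A5 and F33D11.16 (1.08 to 14.6 FPKM). They were followed by T26H5.9 (1.60 to 20.7 FPKM), catp-3 (6.39 to 74.0 FPKM), C06B3.7 (1.69 to 17.4 FPKM) and C50F7.5 (1.02 to 10.04 FPKM). These are genes at 1 FPKM or more in both groups and at 5 or more in at least 1. Their log2 fold changes ran from 3.29 to 4.23. The largest falls were pud-2.2 (69.7 to 1.26 FPKM, listed as pud-2.1, a near-identical copy), the GABA receptor gene unc-49 (46.4 to 9.07 FPKM), Y57G11C.38 (7.62 to 1.52 FPKM), skr-14 (11.205 to 2.54 FPKM), and col-135 (8.78 to 2.22 FPKM). Next were clec-266 (7.76 to 1.99 FPKM), skr-7 (19.99 to 5.29 FPKM), ttr-50 (31.8 to 8.58 FPKM), vet-2 (10.8 to 2.96 FPKM) and the caveolin gene cav-1 (41.2 to 11.6 FPKM). All 20 had the smallest adjusted p that the authors' deposited table holds, 0.000207.

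Genes of the protein synthesis machinery split by kind. Of the cytosolic ribosomal protein genes, 0 rose and 0 fell of 82 tested (0 and 0 adjusted over the list alone), with a median of -0.055 (0.30 when centred). Falls were rarer than among other genes (Fisher's exact test, adjusted p = 3.49e-11). The member with the smallest p was rpl-25.1, at 0.34 ± 0.15 in the authors' deposited table (adjusted p = 0.0553). Of the mitochondrial ribosomal protein genes, 0 rose and 35 fell of 70 tested (0 and 35 adjusted over the list alone), with a median of -0.40 (-0.051 when centred). Examples were mrps-34 at -0.63 ± 0.16, mrpl-18 at -0.59 ± 0.16, mrps-10 at -0.57 ± 0.17 and mrpl-40 at -0.56 ± 0.16. Of the ribosome biogenesis list, 2 rose and 35 fell of 64 tested (2 and 36 adjusted over the list alone), with a median of -0.41 (-0.063 when centred). rpoa-12 and rpac-19, subunits of RNA polymerase I, fell by 0.80 and 0.71 on the log2 scale and the exosome gene exos-2 by 0.70, by the authors' deposited table. Among the members that rose was cebp-1 (0.85 ± 0.20), which encodes a bZIP transcription factor and not a ribosome assembly factor. Of the rRNA methylation genes, 0 rose and 4 fell of 7 tested (0 and 4 adjusted over the list alone), and the list median was -0.46 (-0.11 when centred). The members that fell were nsun-4 (-0.73 ± 0.17), nsun-5 (-0.56 ± 0.21), nsun-1 (-0.34 ± 0.15, but 0.015 when centred) and the fibrillarin gene fib-1 (-0.46 ± 0.15). Of the translation factors, 1 rose and 23 fell of 49 tested (1 and 24 adjusted over the list alone), with a median of -0.34 (0.011 when centred). Among them were eif-2Bdelta at -0.71 ± 0.18 and ife-3 at -0.60 ± 0.15. Of the tRNA synthetases, 0 rose and 16 fell of 35 tested (0 and 16 adjusted over the list alone), with a median of -0.40 (-0.049 when centred). Among them were rars-2 at -0.79 ± 0.16 and nars-2 at -0.78 ± 0.19. The list also held mcrs-1 (-0.69 ± 0.16), which the name pattern took in although it is not a synthetase gene.

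Genes around methionine changed in both directions, with 3 rises and 4 falls among 23 tested (3 and 2 adjusted over the list alone) and a median of -0.21 (0.14 when centred). By the authors' deposited table, the cystathionine gamma-lyase gene cth-1 and the cystathionine beta-synthase gene cbs-2 rose (0.95 ± 0.17 and 0.95 ± 0.19), and the cysteine synthase family gene cysl-2 and the S-adenosylmethionine synthetase gene sams-3 fell (-0.99 ± 0.22 and -0.71 ± 0.16). Most proteasome subunits fell, with 0 rises and 29 falls among 33 tested (0 and 31 adjusted over the list alone) and a median of -0.52 (-0.17 when centred). Examples were rpn-5 (174 to 110.4 FPKM), rpt-1 (171 to 110.01 FPKM), rpt-4 (173 to 114 FPKM) and rpt-6 (122 to 80.5 FPKM). Of the autophagy genes, 1 rose and 18 fell of 29 tested (1 and 19 adjusted over the list alone), with a median of -0.58 (-0.23 when centred). Here sqst-1, an autophagy receptor gene, rose (0.89 ± 0.16) and atg-13, atg-16.2 and epg-6 fell (-0.74 ± 0.17, -0.73 ± 0.18 and -0.72 ± 0.16 in the authors' deposited table).

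Of the remaining lists, the mitochondrial stress response changed in the largest share of members. Nuclear oxidative phosphorylation genes counted 0 rises and 8 falls among 67 tested (0 and 3 adjusted over the list alone) and had a median of -0.18 (0.17 when centred), with cox-17 at -0.79 ± 0.24 and asb-1 at -0.53 ± 0.15. The mitochondrial genome list holds respiratory chain subunits and the mitochondrial ribosomal RNAs, 7 and 1 of the entries tested. Of these, 0 rose and 0 fell of 8 tested (0 and 0 adjusted over the list alone), with a median of -0.16 (0.20 when centred) and nduo-2 at 0.25 ± 0.17 (adjusted p = 0.194 in the authors' deposited table). The mitochondrial stress response counted 1 rise and 8 falls among 16 tested (1 and 9 adjusted over the list alone), with a median of -0.40 (-0.052 when centred) and hsp-6 falling from 261 to 179 FPKM. The heat shock list counted 3 rises and 6 falls among 22 tested (3 and 6 adjusted over the list alone), with a median of -0.035 (0.32 when centred and 0.0036 when centred on all tested genes) and of 0.097 over entries with 1 gene name, hsf-1 at -0.73 ± 0.15 and hsp-12.3 at 0.67 ± 0.27. The ER stress list counted 0 rises and 3 falls among 21 tested (0 and 3 adjusted over the list alone) and had a median of -0.23 (0.12 when centred), with ire-1 at -0.54 ± 0.16. Oxidative stress genes counted 1 rise and 6 falls among 27 tested (1 and 4 adjusted over the list alone) and had a median of -0.15 (0.20 when centred), with gst-12 at -0.94 ± 0.29 and gst-7 at -0.64 ± 0.16. Lysosomal genes counted 3 rises and 5 falls among 48 tested (3 and 5 adjusted over the list alone), with asp-12 at -0.99 ± 0.18, and a median of -0.050 (0.30 when centred). Of the ribosomal RNA entries, 0 rose and 0 fell of 3 tested (0 and 0 adjusted over the list alone), with a median of -0.34 (0.011 when centred) and rrn-1.1 at -0.34 ± 0.17 in the authors' deposited table (adjusted p = 0.0985). That list holds 20 entries, so its median rests on few of them.

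In total RNA, 15557 genes were tested by Cuffdiff and 7240 had an adjusted p below 0.05 in the authors' deposited table, 2894 higher and 4346 lower in the mutant-labelled group. Of these, 1316 rose and 510 fell by 2-fold or more. With normal p-values from the authors' statistics, 799 passed, 502 higher and 297 lower, 62.8% higher. Rises were over-represented, by Fisher's exact test adjusted over lists, directions and comparisons, among collagens (adjusted p = 1.32e-22), sperm genes (5.27e-09), hypodermis and seam markers (0.000435) and innate immunity genes (0.00403). By the same Fisher's exact test, falls were over-represented among oocyte and germline genes (adjusted p = 3.25e-16), the proteasome (1.25e-11), histones (1.38e-07), ribosome biogenesis (3.69e-05), embryo genes (0.000171), mitochondrial ribosomal proteins (0.000316), autophagy (0.000656), translation factors (0.0121) and tRNA synthetases (0.0429). The balance of rises and falls also depends on the scaling of the groups. The median log2 fold change was -0.04 over all tested genes with a finite fold but -0.35 over the 8484 genes at 5 FPKM or more in both groups. With fold changes centred on that median and tested again with variances divided by libraries, a choice made after seeing the data, 5015 genes were higher and 1135 lower, 81.5% higher against 39.97% as deposited. Against expression-matched random lists, a comparison that such a shift does not alter, the medians of collagens, hypodermis and seam, sperm, innate immunity and muscle lay at the 100th percentile and those of oocyte and germline, embryo, histone and proteasome genes at the 0th. DAF-16 targets (99.8th), lysosomal genes (99.2nd), intestine (99.2nd) and neuron markers (98.1st) also lay in the upper 2.5% and autophagy genes (0.11th) in the lower. The ribosome biogenesis list lay at the 18.7th, mitochondrial ribosomal proteins at the 64.4th and cytosolic ribosomal proteins at the 99.97th percentile.

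**Figure D2:**
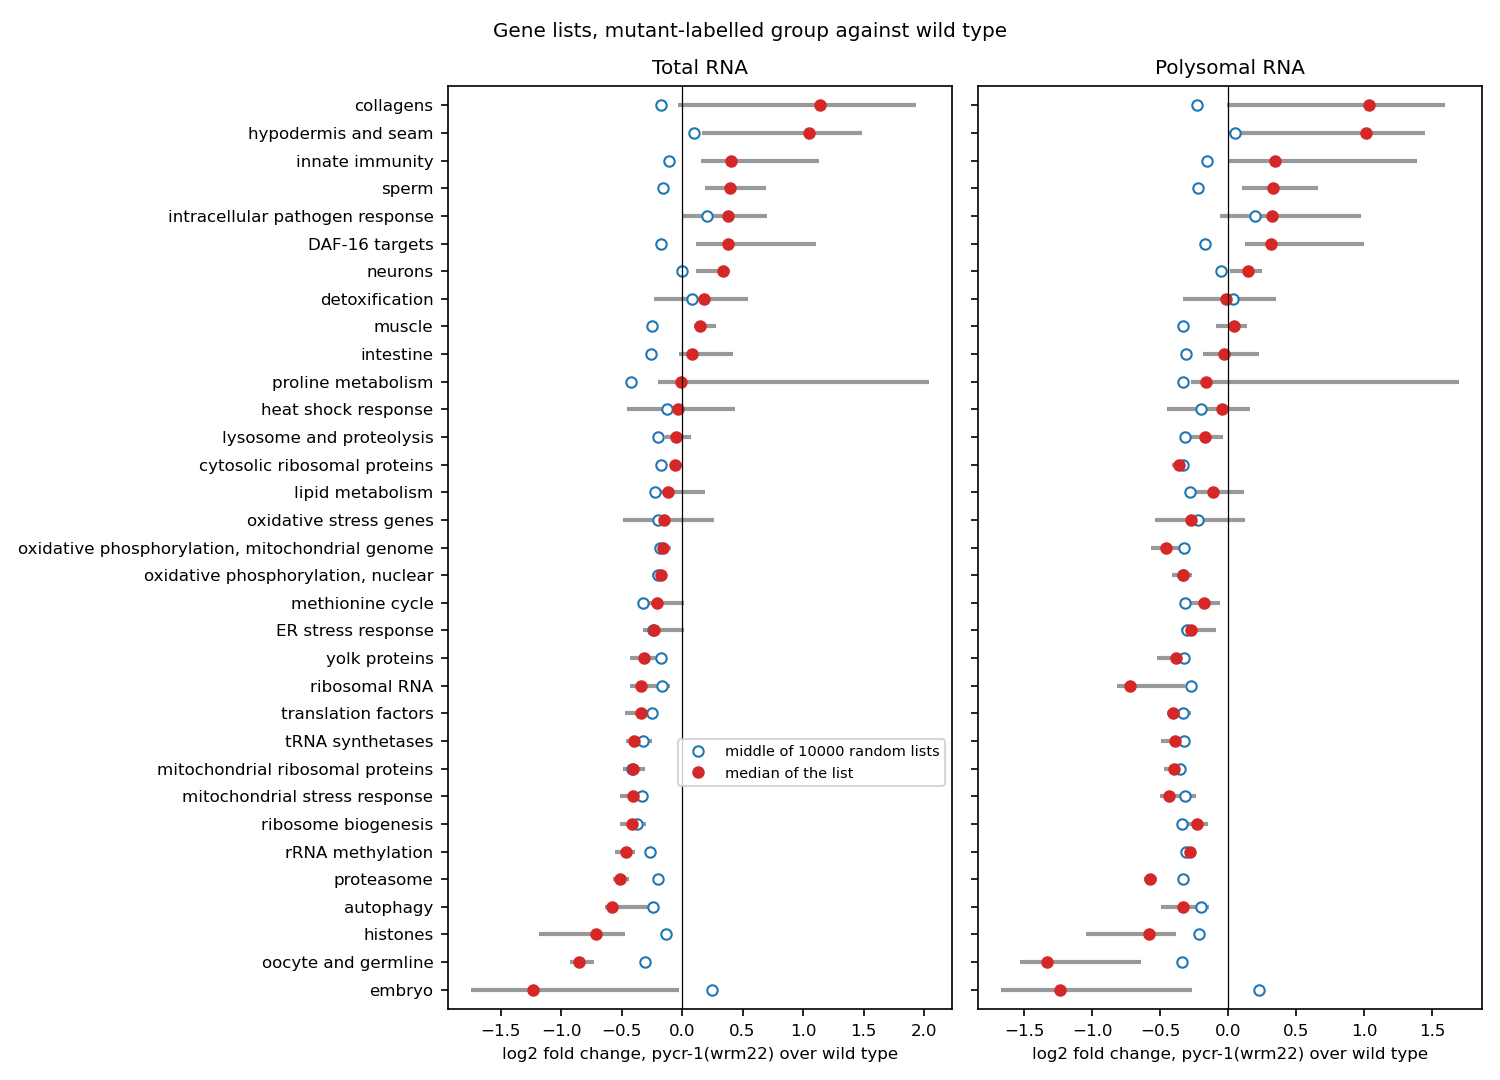
Median log2 fold change of each of the 33 gene lists, pycr-1(wrm22) over wild type, in total RNA (left) and polysomal RNA (right), as red points with grey bars from the lower to the upper quartile of the members and open circles for the middle of 10000 expression-matched random lists. Collagens stood at 1.14 and 1.03 and oocyte and germline genes at -0.85 and -1.33 in total and polysomal RNA.

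In polysomal RNA of the mutant-labelled worms, oocyte, germline and embryo genes were again lower and collagens higher, and many cytosolic ribosomal protein mRNAs fell. Of the latter, 2 rose and 38 fell of 82 tested (2 and 38 adjusted over the list alone), with a median of -0.36 (-0.11 when centred). There, by the authors' deposited table, rpl-38 went from 5333 to 3469 FPKM (-0.62 ± 0.15) and rpl-41.2 from 1143 to 744 FPKM (-0.62 ± 0.17), while the members that rose were rpl-25.1 (0.74 ± 0.17) and rpl-11.2 (0.62 ± 0.15). Of the mitochondrial ribosomal protein genes, 0 rose and 41 fell of 70 tested (0 and 44 adjusted over the list alone), with a median of -0.40 (-0.14 when centred). Among them were mrpl-12 (-0.64 ± 0.16) and mrps-33 (-0.64 ± 0.17). Of the ribosome biogenesis list, 1 rose and 11 fell of 64 tested (1 and 0 adjusted over the list alone). Its median was -0.23 (0.023 when centred). That median lay at the 98.6th percentile of expression-matched random lists, whose middle was -0.34, so the list stood higher than most of them. Falls were not over-represented, at 17.2% of members against 23.9% of other genes (Fisher's exact test, adjusted p = 0.322). cebp-1 was the member that rose (0.70 ± 0.19), and exos-7, exos-2 and sbds-1 fell by 0.46, 0.44 and 0.44 on the log2 scale in the authors' deposited table. Of the rRNA methylation genes, 0 rose and 2 fell of 7 tested (0 and 0 adjusted over the list alone), with a median of -0.28 (-0.025 when centred) and nsun-4 at -0.44 ± 0.17 and fib-1 at -0.33 ± 0.15. Translation factors counted 2 rises and 30 falls among 49 tested (2 and 32 adjusted over the list alone), with a median of -0.40 (-0.15 when centred) and ife-3 going from 424 to 254 FPKM and iff-1 from 2046 to 1329.9 FPKM. tRNA synthetases counted 0 rises and 21 falls among 35 tested (0 and 24 adjusted over the list alone), with a median of -0.39 (-0.14 when centred), mars-1 at -0.56 ± 0.17 and lars-2 at -0.54 ± 0.16. The proteasome counted 1 rise and 31 falls among 33 tested (1 and 32 adjusted over the list alone), with a median of -0.57 (-0.32 when centred), rpt-5 at -0.67 ± 0.15 and pbs-6 at -0.66 ± 0.15.

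Oocyte and germline genes counted 0 rises and 33 falls among 40 tested (0 and 33 adjusted over the list alone), with a median of -1.33 (-1.07 when centred). oma-2 fell from 68.9 to 18.97 FPKM, egg-1 from 139 to 42.1 FPKM, meg-1 from 19.5 to 5.93 FPKM and meg-2 from 4.69 to 1.29 FPKM, by the authors' deposited table. Embryo genes counted 1 rise and 23 falls among 45 tested (1 and 23 adjusted over the list alone), with a median of -1.24 (-0.98 when centred). Histones counted 2 rises and 28 falls among 55 tested (2 and 28 adjusted over the list alone), with a median of -0.58 (-0.33 when centred), and his-1 fell by 1.66 and his-31 by 1.69 on the log2 scale. his-17, also on that list, is not a core histone gene (-1.64 ± 0.32). Collagens counted 78 rises and 21 falls among 135 tested (79 and 23 adjusted over the list alone). Here col-182 (1.43 to 6.62 FPKM), col-174 (0.969 to 3.82 FPKM) and bli-2 (7.89 to 30.05 FPKM) were higher and col-135 (19.4 to 4.52 FPKM) lower. Hypodermis and seam markers counted 9 rises and 1 fall among 16 tested (9 and 1 adjusted over the list alone), and ptr-4 (1.73 ± 0.21) and mlt-10 (1.65 ± 0.21) rose. The list median was 1.02 over all tested members and -0.030 over the members at 5 FPKM or more. Sperm genes counted 32 rises and 2 falls among 92 tested (30 and 1 adjusted over the list alone), with spe-47 at 1.13 ± 0.29.

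Innate immunity genes counted 18 rises and 0 falls among 44 tested (18 and 0 adjusted over the list alone). By the authors' deposited table, cnc-4 went from 4.02 to 46.1 FPKM, irg-2 from 1.85 to 14.9 FPKM and ilys-3 from 0.177 to 2.01 FPKM. DAF-16 targets counted 7 rises and 0 falls among 23 tested (7 and 0 adjusted over the list alone), with dod-3 (2.09 ± 0.30), lys-7 (1.76 ± 0.16), ftn-1 (1.61 ± 0.57) and gpdh-1 (1.503 ± 0.21). Detoxification genes counted 33 rises and 31 falls among 191 tested (28 and 26 adjusted over the list alone), with a median of -0.014 (0.24 when centred and 0.059 when centred on all tested genes). The intracellular pathogen response counted 2 rises and 1 fall among 13 tested (2 and 1 adjusted over the list alone) and lipid metabolism 5 rises and 7 falls among 46 tested (3 and 6 adjusted over the list alone). The lipid metabolism median was -0.11 (0.14 when centred). cyp-14A5 went from 11.97 to 181 FPKM, pals-4 from 0.704 to 0.262 FPKM and lipl-2 from 0.801 to 2.84 FPKM, by the authors' deposited table. The methionine cycle list counted 2 rises and 7 falls among 23 tested (2 and 6 adjusted over the list alone) and had a median of -0.18 (0.080 when centred), with cth-1 (0.97 ± 0.17) and cbs-2 (0.84 ± 0.21) higher and cysl-2 (-1.0998 ± 0.20) and sams-3 (-0.56 ± 0.16) lower. Nuclear oxidative phosphorylation genes counted 0 rises and 31 falls among 67 tested (0 and 30 adjusted over the list alone), with a median of -0.33 (-0.073 when centred), cox-11 at -0.63 ± 0.18 and cox-15 at -0.60 ± 0.15. The mitochondrial genome list counted 0 rises and 7 falls among 9 tested (0 and 7 adjusted over the list alone), 5 falls among 7 entries of subunits and 2 among 2 of ribosomal RNA, with a median of -0.46 (-0.20 when centred) and nduo-2 at -0.86 ± 0.39.

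In the mitochondrial stress response, 0 rose and 9 fell of 16 tested (1 and 10 adjusted over the list alone), with a median of -0.44 (-0.18 when centred), hsp-6 at -0.68 ± 0.15 and clpp-1 at -0.70 ± 0.24. The heat shock list counted 2 rises and 6 falls among 20 tested (2 and 6 adjusted over the list alone) and had a median of -0.045 (0.21 when centred and 0.029 when centred on all tested genes) and of 0.032 over entries with 1 gene name, with the small heat shock protein gene sip-1 going from 1218 to 591 FPKM. The ER list counted 0 rises and 6 falls among 21 tested (0 and 2 adjusted over the list alone), with a median of -0.28 (-0.019 when centred). Oxidative stress genes counted 1 rise and 6 falls among 27 tested (1 and 5 adjusted over the list alone), with a median of -0.28 (-0.020 when centred), and autophagy genes 1 rise and 10 falls among 29 tested (1 and 7 adjusted over the list alone), the latter with a median of -0.33 (-0.077 when centred). Among their members in the authors' deposited table, cnx-1 stood at -0.52 ± 0.15, prdx-3 at -0.54 ± 0.15, atg-5 at -0.64 ± 0.21 and sqst-1 at 0.79 ± 0.16. Muscle markers counted 1 rise and 1 fall among 30 tested (0 and 0 adjusted over the list alone). Intestine markers counted 0 rises and 1 fall among 19 tested (0 and 0 adjusted over the list alone), and neuron markers 2 rises and 1 fall among 29 tested (0 and 0 adjusted over the list alone). mlp-1 stood at 0.45 ± 0.16, gut-2 at -0.56 ± 0.22 and flp-9 at 0.68 ± 0.21 in the authors' deposited table, and the intestine median at -0.034 (0.22 when centred and 0.039 when centred on all tested genes). Yolk protein genes counted 0 rises and 1 fall among 6 tested (0 and 0 adjusted over the list alone), with a median of -0.38 (-0.13 when centred) and vit-3 at -0.53 ± 0.18. Ribosomal RNA entries counted 0 rises and 2 falls among 3 tested (0 and 2 adjusted over the list alone), with a median of -0.72 (-0.46 when centred) and rrn-3.1 at -0.82 ± 0.21. Only 3 of the 20 entries were tested. Their values differed widely, with rrn-1.1 at 14.7 and rrn-3.1 at 5179 FPKM in wild-type polysomal RNA, so they are uncertain measures of ribosomal RNA. Lysosomal genes counted 3 rises and 8 falls among 48 tested (0 and 5 adjusted over the list alone), with asp-12 at -1.14 ± 0.17 and a median of -0.17 (0.082 when centred).

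The largest rises in polysomal RNA in the authors' deposited table were ugt-24 (1.31 to 33.3 FPKM), F54B8.4 (9.54 to 169 FPKM), cyp-14A5, Y58A7A.5 (5.64 to 84.4 FPKM), and catp-3 (7.13 to 100.2 FPKM). Next were T26H5.9 (2.02 to 28.1 FPKM), parg-2 (2.98 to 37.6 FPKM), cnc-4, C50F7.5 (1.95 to 21.7 FPKM) and C06B3.7 (2.94 to 27.2 FPKM). The largest falls were C29F7.10 (6.27 to 1.14 FPKM), F46E10.2 (6.50 to 1.35 FPKM), the small nuclear RNA C27H5.11 (6.16 to 1.34 FPKM), skr-14 (25.2 to 5.82 FPKM) and col-135, followed by rgs-11 (5.92 to 1.40 FPKM), F54F7.6 (8.52 to 2.02 FPKM), skr-15 (6.32 to 1.56 FPKM), R04D3.3 (45.9 to 11.9 FPKM) and skr-7 (45.6 to 12.097 FPKM). skr-7, skr-14 and skr-15 belong to the Skp1-related gene family. Of 14696 genes tested by Cuffdiff in polysomal RNA, 5691 passed the threshold in the authors' deposited table, 2180 higher and 3511 lower in the mutant-labelled group, and 1040 rose and 607 fell by 2-fold or more. With normal p-values from the statistics, 661 passed, 383 higher and 278 lower, 57.9% higher. The median log2 fold change was -0.07 over all tested genes and -0.26 over those at 5 FPKM or more, and centred on the latter and tested again with variances divided by libraries 3384 were higher and 1117 lower, 75.2% higher against 38.3% as deposited. Over-representation of rises by Fisher's exact test had an adjusted p of 1.72e-28 for collagens, 9.42e-06 for sperm genes, 0.000101 for innate immunity and 0.000479 for hypodermis and seam markers. For falls it was 3.97e-16 for the proteasome, 1.64e-13 for oocyte and germline genes, 4.61e-09 for mitochondrial and 4.77e-05 for cytosolic ribosomal proteins. By the same Fisher's exact test it was 1.79e-07 for translation factors, 2.63e-05 for tRNA synthetases, 7.76e-05 for histones and 0.000256 for nuclear oxidative phosphorylation. It was 0.000268 for embryo genes, 0.00263 for the mitochondrial genome list and 0.0114 for the mitochondrial stress response. The cytosolic ribosomal protein median lay at the 11.7th percentile of expression-matched random lists, whose middle was -0.33. Muscle markers lay at the 100th percentile of such lists, intestine markers at the 98.6th and neuron markers at the 92.7th.

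The changes in both fractions were set side by side. Across the 14335 genes tested in both, Spearman's rho between the log2 fold changes was 0.866 and 88.7% had the same sign, a description across genes, which are not independent replicates. In the authors' deposited table, 1842 genes rose and 2860 fell in both fractions, where independent lists would share 406 and 1029. These numbers ignore that the labels give both fractions of a strain the same replicate numbers and 1 harvest per genotype and replicate, so the fractions are paired by label. A further 11 genes passed the threshold in opposite directions. Among them nspc-7 went from 14.4 to 8.51 FPKM in total and from 11.3 to 30.8 FPKM in polysomal RNA, and T09B9.1 from 13.6 to 6.07 FPKM and from 1.83 to 2.84 FPKM. The CPEB family gene cpb-1 fell in total and rose in polysomal RNA (-0.51 ± 0.16 and 0.49 ± 0.21), and rpa-4 (0.62 ± 0.21 and -0.92 ± 0.41) and C33F10.11 (0.60 ± 0.17 and -0.65 ± 0.20) went the other way, by the authors' deposited table. With variances divided by libraries, cpb-1 and rpa-4 did not pass in polysomal RNA.

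In the polysomal fraction of wild-type worms, small nucleolar and small nuclear RNAs had low median ratios, and oocyte and germline genes were depleted more often than other genes. Small nucleolar RNAs had a median log2 ratio of polysomal to total RNA of -4.69 over 136 tested entries and small nuclear RNAs of -4.08 over 38, against 0.12 over 14039 protein-coding genes. Of these, 32, 16 and 3515 passed the threshold as depleted, a share no larger for small nucleolar RNAs than for protein-coding genes. The ribosomal RNA list had a median of 0.30, with 1 enriched and 0 depleted of 3 tested. The RNase P RNA gene rpr-1 went from 7139 to 60.9 FPKM and lfor-1 from 964 to 4.74 FPKM in the authors' deposited table. Histones, many of whose mRNAs lack a poly(A) tail, counted 6 enriched and 47 depleted of 68 tested (7 and 47 adjusted over the list alone), with a median of -2.89. The mitochondrial genome list, 7 entries of subunits, whose mRNAs are translated on other ribosomes, and 1 of ribosomal RNA, counted 0 enriched and 8 depleted of 8 tested (0 and 8 adjusted over the list alone), with a median of -2.61. Oocyte and germline genes counted 8 enriched and 28 depleted of 40 tested (8 and 29 adjusted over the list alone), with a median of -0.86. The 4 with the largest changes past the threshold, nos-2, pos-1, spn-4 and glp-1, had log2 ratios of -5.11 ± 0.56, -3.48 ± 0.18, -3.04 ± 0.16 and -2.15 ± 0.16 in the authors' deposited table. Embryo genes counted 12 enriched and 10 depleted of 50 tested (12 and 8 adjusted over the list alone), with a median of 0.23 at the 98.3rd percentile of expression-matched random lists, and their largest change past the threshold was that of pal-1 at -3.16 ± 0.23. Muscle markers (24 enriched and 0 depleted of 30), detoxification genes (110 enriched and 6 depleted of 187), innate immunity genes (26 enriched and 1 depleted of 40), collagens (94 enriched and 4 depleted of 134) and the proteasome (27 enriched and 1 depleted of 33) were mostly enriched. By the authors' deposited table, the troponin gene tni-3 stood at 1.36 ± 0.18, nlp-29 at 1.48 ± 0.24 and pas-5 at 1.14 ± 0.15, while cyp-33C3 was depleted (-2.70 ± 0.36). Enrichment was over-represented by Fisher's exact test among collagens (adjusted p = 1.52e-26) and muscle markers (2.53e-09), and depletion among oocyte and germline genes (1.13e-07).

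Cytosolic ribosomal protein mRNAs in wild type counted 51 enriched and 8 depleted of 82 tested (54 and 8 adjusted over the list alone) with a median of 0.44, below most random lists of like expression, whose middle was 0.61. rpl-41.2 and rpl-41.1, which encode the smallest ribosomal protein, stood at -3.08 ± 0.17 and -2.29 ± 0.18 in the authors' deposited table, and rpl-25.1 at -2.33 ± 0.17. Translation factors counted 34 enriched and 5 depleted of 49 tested (34 and 5 adjusted over the list alone), and mitochondrial ribosomal proteins 35 enriched and 1 depleted of 70 tested (35 and 1 adjusted over the list alone). The methionine cycle counted 14 enriched and 1 depleted of 23 tested (14 and 1 adjusted over the list alone), and nuclear oxidative phosphorylation 54 enriched and 2 depleted of 67 tested (54 and 2 adjusted over the list alone). pycr-1 stood at 1.36 ± 0.21, inf-1 at 1.05 ± 0.14, mrpl-12 at 0.95 ± 0.16, cth-2 at 1.02 ± 0.16 and mai-2 at 1.296 ± 0.15 in the authors' deposited table. The largest enrichments were C45G9.12 (2.37 to 9.13 FPKM), B0416.7 (5.17 to 18.6 FPKM), irg-1 (3.86 to 13.1 FPKM), irg-3 (6.16 to 20.7 FPKM) and ttr-5 (14.1 to 46.9 FPKM), followed by Y57G11B.2, dlc-3, ttr-6, ZK105.1 and F47G3.4. The largest depletions after lfor-1 and rpr-1 were ZK185.9 (32334 to 281 FPKM), F52D4.1 (822 to 7.24 FPKM) and mrpr-1 (4468 to 74.4 FPKM), the RNA of RNase MRP. Of 15266 genes tested by Cuffdiff, 7878 passed the threshold in the authors' deposited table, 3765 enriched and 4113 depleted. FPKM values are shares of each library, so the ratios say how a gene stood relative to others, and the median ratio was 0.05 over all tested genes.

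In the mutant-labelled worms the polysomal fraction was enriched and depleted in largely the same genes. Of 15425 genes tested, 7841 passed the threshold in the authors' deposited table, 3682 enriched and 4159 depleted. In both strains, 3094 genes were enriched and 3491 depleted, where independent lists would share 929 and 1089. Spearman's rho between the strains' log2 ratios was 0.928 across 14665 genes, from libraries that are not shared. Centred on the genes at 5 FPKM or more, whose median ratio was 0.11, and tested with variances divided by libraries, 37.8% of calls were enriched against 46.96% as deposited. Cytosolic ribosomal protein mRNAs counted 7 enriched and 13 depleted of 82 tested (6 and 12 adjusted over the list alone) with a median of 0.12 (0.0044 when centred), below all random lists of like expression, whose middle was 0.47. There rps-12 went from 3489.6 to 1267 FPKM and rpl-41.2 from 9075 to 744 FPKM in the authors' deposited table. Ribosome biogenesis counted 26 enriched and 7 depleted of 64 tested (26 and 7 adjusted over the list alone), with fib-1 at 0.84 ± 0.15 and garr-1 at 1.01 ± 0.15. Oocyte and germline genes counted 8 enriched and 27 depleted of 40 tested (8 and 27 adjusted over the list alone), with a median of -1.49, egg-4 standing at -2.58 ± 0.15 and nos-2 at -4.93 ± 0.39. Histones counted 6 enriched and 44 depleted of 63 tested (7 and 44 adjusted over the list alone), and the mitochondrial genome list 0 enriched and 9 depleted of 9 tested (0 and 9 adjusted over the list alone), 2 of them ribosomal RNA entries. The largest enrichments held antimicrobial peptide genes, nlp-30 (4.42 to 14.5 FPKM), nlp-29 (43.4 to 131 FPKM), nlp-27 (139 to 404 FPKM), nlp-33 (45.9 to 129 FPKM) and cnc-4 (16.40 to 46.1 FPKM), beside nspc-7, nspe-7, ttr-6, ttr-8 and the heme transport gene hrg-4. The largest depletions were lfor-1, rpr-1, C18C4.17, CD4.18 and F52D4.1.

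The difference between the fractions, that is the log2 fold change in polysomal RNA minus that in total RNA, asks whether polysome association differed between the strains. As a group, cytosolic ribosomal protein mRNAs were lower, with a median difference of -0.29. Of 81 tested, 78 were below 0, and 10000 random lists of like expression had medians from -0.19 to -0.07. In polysomal RNA the median of these mRNAs was -0.36 against -0.33 for the middle of random lists, and in total RNA -0.055 against -0.17. They thus stood apart from genes of like expression more in total than in polysomal RNA. Oocyte and germline mRNAs were lower too, with a median of -0.41, 30 of 40 below 0 and random lists down to -0.18. The same held for collagens (-0.24, 118 of 134 below 0) and detoxification genes (-0.14, 148 members below 0). Ribosome biogenesis mRNAs were higher, with a median of 0.15, 55 of 64 above 0 and random lists up to 0.09. Also higher were histones (0.09) and autophagy genes (0.16, 99.93rd percentile). The median difference was -0.04 over all tested genes and -0.02 over those at 5 FPKM or more. Mitochondrial ribosomal proteins (-0.01), translation factors (-0.03), tRNA synthetases (-0.04), the methionine cycle (-0.10) and the proteasome (-0.07) lay within the range of their random lists. Translation factors (99.3rd percentile), the mitochondrial genome list (0.370th), neuron markers (1.49th) and ribosomal RNA (1.36th) lay in the outer 5%, and the lists not named here within the central 95%.

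**Figure D3:**
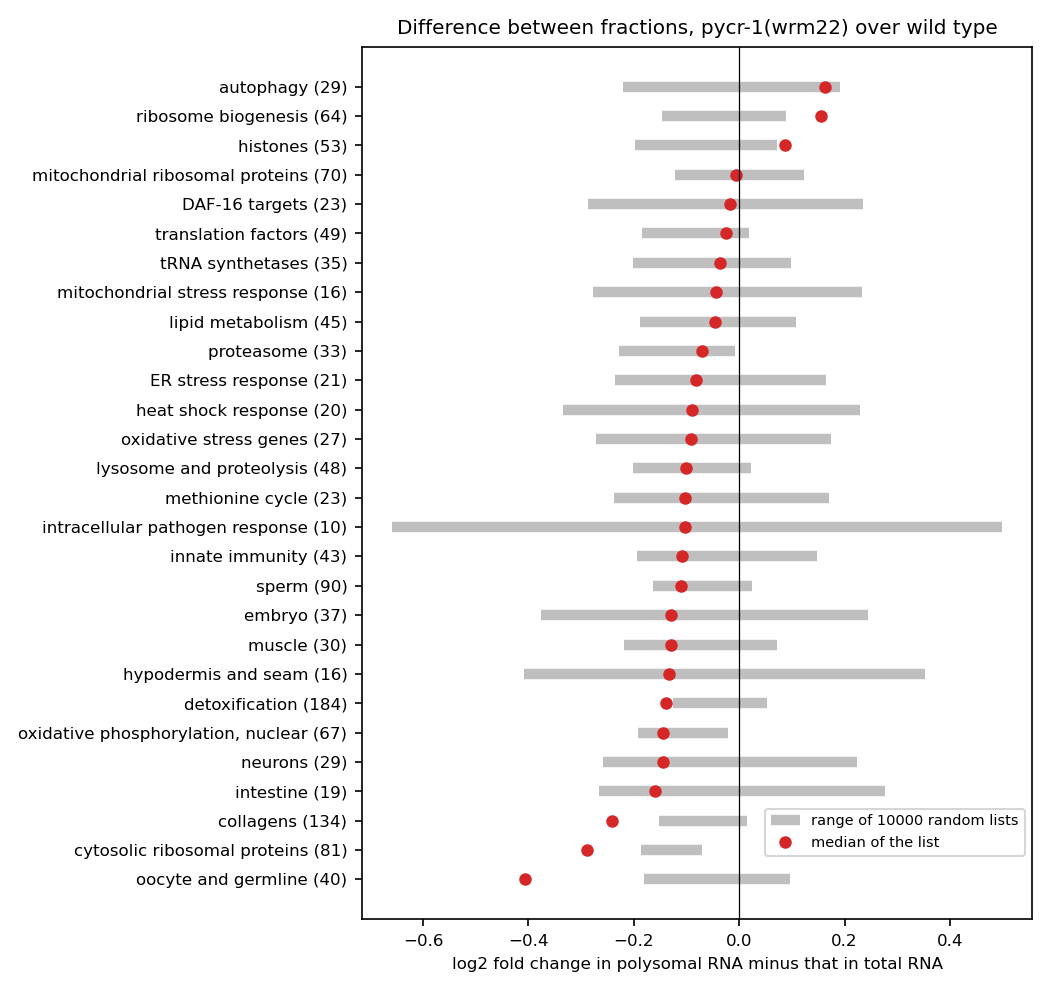
Median difference of the log2 fold changes (polysomal minus total RNA, pycr-1(wrm22) over wild type) for the gene lists with at least 10 tested members, number tested in parentheses, as red points over grey bars that span the medians of 10000 expression-matched random lists. Oocyte and germline genes (-0.41), cytosolic ribosomal proteins (-0.29) and collagens (-0.24) lay below their bars and ribosome biogenesis (0.15) above.

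Single genes were tested with a Wald test on the authors' statistics, which took all libraries as independent although both fractions share replicate numbers. With these as they stand, 3 of 14302 genes passed an adjusted p of 0.05, against 32 at an unadjusted p below 0.05. They were pud-2.2, with a difference of 6.32, and 2 short noncoding entries, C18H9.12 of 94 bp (2.02) and the small nucleolar RNA Y53F4B.47 of 80 bp (0.83). For this difference the naming floor was 1 FPKM in all 4 groups, and pud-2.2 lay under it in wild-type polysomal RNA (0.882). The implied SE of the noncoding entries, 0.0909 and 0.0134, lay below the 1st percentile of all tested, 0.386, and neither entry passed in any of the authors' comparisons, with smallest adjusted p-values of 0.183 and 0.170. With the variance divided by the number of libraries, a test chosen after seeing the data, 22 passed, 11 higher and 11 lower, against 560 at an unadjusted p below 0.05. The higher ones included unc-49 (2.59 ± 0.35), which stood at 46.4 FPKM in wild-type total RNA and at 5.62, 9.07 and 6.602 FPKM in wild-type polysomal, mutant-labelled total and mutant-labelled polysomal RNA. Others were nspc-7 (2.21 ± 0.35), Y57G11C.38 (2.32 ± 0.39), T09B9.1 (1.79 ± 0.31), K07H8.9 (1.44 ± 0.30), the spermatogenesis regulator spe-44 (1.36 ± 0.29) and M116.5 (1.01 ± 0.25). The lower ones included F33D11.16 (-4.60 ± 0.69), C27H5.11 (-2.47 ± 0.61), C33F10.11 (-1.25 ± 0.26), R10E4.7 (-1.07 ± 0.26), W05F2.3 (-0.97 ± 0.22), the eggshell proteoglycan gene cpg-1 (-0.91 ± 0.22) and C33A12.3 (-0.84 ± 0.20). Adjusted over the list alone with that test, 15 oocyte and germline genes were lower and 1 higher, and 0 of 81 cytosolic ribosomal protein and 0 of 64 ribosome biogenesis genes passed. With the Wald test as planned, 0 ribosomal protein genes passed, so their shift was seen in the list median, not in single genes. In simulated data with a difference of 1 on the log2 scale, the planned test recovered 3% of the changed genes and the test with divided variance 51%, over 14302 genes. That noise was drawn with the divided variance, so these shares do not show which test is right.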

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

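The tests of transcript abundance and of exchanged labels given here were chosen only after the result was seen, as was the Wald test with divided variances.

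The fold changes of 3 genes differed between the fractions by the planned Wald test. For C18H9.12, a noncoding entry of 94 bp on chromosome II (6691986 to 6692079), the polysomal minus total log2 fold change was 2.02, with 78.2 FPKM in wild-type total, 36.3 in wild-type polysomal, 9.49 in mutant-labelled total and 17.9 in mutant-labelled polysomal RNA. For Y53F4B.47, a small nucleolar RNA of 80 bp on chromosome II (15025814 to 15025893), it was 0.83, and for pud-2.2 it was 6.32 with 69.7 FPKM in wild-type total RNA and 0.882, 1.26 and 1.28 in the other groups. None of the authors' comparisons passed for C18H9.12 (adjusted p = 0.183, 0.703, 0.562 and 1) or Y53F4B.47 (0.170, 0.803, 0.343 and 0.337), so both calls rest on small implied SEs of 0.0909 and 0.0134. pud-2.2 is listed under the name of its near-identical copy pud-2.1, so reads of either are uncertain. The ribosomal RNA entry rrn-2.1 was listed at 830999 FPKM in mutant-labelled total RNA and at 0 in the other groups, and was not tested by the authors. Together with it, entries that are not protein-coding summed to 1126160 FPKM in that group against 292110 in wild-type total RNA, and to 295161 without it, so this 1 entry made nearly the whole difference.

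Cytosolic ribosomal protein mRNAs had a median difference of -0.29 between the fractions. Their median lay at the 11.7th percentile of expression-matched random lists in polysomal RNA and at the 99.97th in total RNA. They thus stood apart from such genes more in total RNA. Short coding sequences could account for a lower place in the gradient, since the median coding length was 441 bp against 1080 bp in other genes, but among 10000 random lists matched on coding length the lowest median was -0.24. High abundance could act through the scaling, but the median lay below all expression-matched random lists, the lowest of which was at -0.19. Such lists without any member reached -0.17, an outcome the first comparison had all but fixed, so it adds no further weight. Lists matched on both length and expression reached -0.18. A change in the tissues or the germline of the worms could move the difference as well and stays open, since oocyte and germline mRNAs stood at -0.41 in the same difference and at -0.85 in total RNA, and collagens at -0.24. The genotype also stays open and was not tested beyond the group labels, so a change in translation of these mRNAs is a hypothesis.

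pycr-1 was higher in both mutant-labelled groups, at 2.05 in total RNA and 1.70 in polysomal RNA. X genes as a whole did not rise as much. The median of 2134 tested X genes was 0.16, and pycr-1 stood at the 97.6th percentile of them. That median cannot test a larger share of the particular tissues that express pycr-1, since collagens had a median of 1.14 beside it. Such a share stays open. A change of the whole region is argued against by the 9 tested neighbours of pycr-1 within 50 kb, whose median was 0.28 and largest value 0.76. Exchanged labels would give the same direction in both fractions, as seen, and cannot be told apart from an allele that leaves or raises the RNA. What the allele does to the transcript was not tested.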

How the results depend on the processing

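The alternatives with variances divided by libraries, with centring on genes at 5 FPKM or more, with every gene ID counted and with lists matched on coding length were chosen only after the data were seen. No paired analysis was possible because the table holds no values per library, and for the same reason leaving out each replicate, another pseudocount per library, the replicate block and other splits of the samples were not run. The depth is unknown, so what it limits could not be weighed.

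Higher minimums and the stricter threshold keep fewer genes by construction. With a 2-fold minimum, 1826 genes passed in total RNA (72.1% higher) and 1647 in polysomal RNA (63.1%), and between fractions 3762 in wild type (29.6% enriched) and 3010 in the mutant-labelled strain (18.3%). With 5 FPKM or more in both groups, 4741 passed in total RNA (21.6% higher), 3771 in polysomal RNA (23.5% higher) and 5207 between fractions in the mutant-labelled strain, and with 5 FPKM in all 4 groups 2988 genes passed in the same direction in both fractions. The cause of the changed shares was not tested. At an adjusted p of 0.01, 3695 passed in polysomal RNA and 2957 in the same direction in both fractions. With normal p-values from the statistics, 799 passed in total RNA (62.8% higher), 661 in polysomal RNA (57.9%), 4084 between fractions in wild type (35.7%) and 2788 in the mutant-labelled strain (24.6%), since these use the variance without division by libraries. As deposited, the shares were 39.97%, 38.3%, 47.8% and 46.96%, and the cause of the difference was not tested. The difference between strains in polysome association gave 22 genes with divided variances and 25 when also centred, against 3 as planned.

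Centred on genes at 5 FPKM or more and tested with variances divided by libraries, 6150 genes passed in total RNA and 4501 in polysomal RNA, and 3921 and 3226 of them passed in the same direction as deposited. Centring list medians this way added 0.35 in total and 0.26 in polysomal RNA, which by construction turned 13 of 33 medians in total RNA from below to above 0. These were proline metabolism (0.34), heat shock (0.32), lysosome (0.30), cytosolic ribosomal proteins (0.30), lipid metabolism (0.23), oxidative stress (0.20), the mitochondrial genome list (0.20), nuclear oxidative phosphorylation (0.17), the methionine cycle (0.14), ER stress (0.12), yolk proteins (0.037), translation factors (0.011) and ribosomal RNA (0.011). In polysomal RNA it turned 8, detoxification (0.24), intestine (0.22), heat shock (0.21), lipid metabolism (0.14), proline metabolism (0.093), lysosome (0.082), the methionine cycle (0.080) and ribosome biogenesis (0.023). Centring on all tested genes turned proline metabolism (0.032) and heat shock (0.0036) in total RNA and detoxification (0.059), intestine (0.039) and heat shock (0.029) in polysomal RNA. Over members at 5 FPKM or more, the hypodermis and seam median was -0.0097 in total and -0.030 in polysomal RNA and the detoxification median -0.0051 in total RNA, and over entries with 1 gene name the heat shock median was 0.097 and 0.032. The cause of these was not tested. The number of list tests past the threshold was 151, and 128 to 152 under its alternatives.

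Among 588 gene results chosen by the naming rule, over the 4 comparisons, 257 lost the threshold with normal p-values, 19 with divided variances and 12 with adjustment over 1 comparison alone. With centring on genes at 5 FPKM or more and divided variances together, 102 lost it, and nsun-1 in total RNA turned from below 0 to 0.015. A change of sign was counted only for genes past the threshold in either setting.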

Other observations

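The test of the cuticle genes against muscle and intestine was chosen only after the result was seen, and the enrichment of annotated terms was run without a prior list.

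Annotated terms of 10 to 500 genes, as the authors' deposited table pairs them with genes, were tested by a one-sided Fisher's exact test over 3730 tests, of which 638 passed after Benjamini-Hochberg adjustment. Among genes that fell in total RNA were 134 of 158 cell cycle genes (Fisher's exact test, adjusted p = 3.94e-41), 56 of 57 DNA replication genes, 52 of 63 P granule genes, 32 of 36 nuclear pore genes and 33 of 36 spliceosomal complex genes, where 31.5% of all annotated genes fell. Among genes that rose were 91 of 161 protein dephosphorylation genes (Fisher's exact test, adjusted p = 1.38e-27), 65 of 94 genes of regulation of cell shape, 64 of 102 protein tyrosine phosphatase genes and 39 of 93 metalloendopeptidase genes, where 17.04% rose. In polysomal RNA, 33 of 35 proteasome complex genes (Fisher's exact test, adjusted p = 2.06e-15) and 193 of 381 mitochondrion genes (8.36e-23) fell, where 26.3% of all annotated genes fell, and 80 of 266 innate immune response genes rose (2.59e-11), where 13.3% rose. These counts share the scaling limits given for the fold changes, and the tests did not match genes on expression.

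The median log2 fold change in total RNA was -0.27 on chromosome I, -0.29 on III, -0.11 on II, -0.00 on IV, 0.13 on V and 0.16 on X, with 382 genes higher and 290 lower on X against 319 and 893 on III. Differences between chromosomes were not tested, and the median of X genes outside the gene lists stood at the 30.97th percentile of expression-matched autosomal lists.

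Germline and embryo genes were lower and cuticle genes higher in the mutant-labelled groups. A smaller share of germline RNA may raise all body tissues alike, and muscle markers lay above all expression-matched random lists. Collagens exceeded muscle and intestine markers by a median of 1.01 (95% bootstrap interval 0.71 to 1.34 over genes). A rise alike in all tissues would thus not be the whole cause of the cuticle part. The test was written after these medians were seen. Its interval takes genes as independent and does not measure the spread between libraries. For the germline part, genes on chromosome X, largely silent in the germline, had a median of 0.16 against 0.17 for expression-matched autosomal lists (30.97th percentile), which met the bound written beforehand against that cause, but by less than the spread of the lists (SD 0.02). That the spread must be exceeded was required only after the value was seen, so a smaller germline share cannot be told apart from other causes. A different stage of the worms cannot be told apart from a change of the epidermis and stays open, as does the genotype, untested: 21 molting genes outside the lists had a median of 1.51, but molting genes act in the epidermis and some were known to be higher before this test was written, so it repeats the cuticle part and does not bear on the germline part.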
